A study of Arabidopsis thaliana with 10 samples.

How the data were processed

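The material was total nucleic acid from shoots or roots of grafted Arabidopsis plants grown at 20 °C with 10 h of light, pooled from 3 to 4 grafts per library, and small RNA was cloned with an Illumina small RNA kit, per the labels. The 10 libraries form 5 groups of 2, called biological replicates in the series description. The deposited counts are raw numbers of reads per distinct small RNA sequence, with no normalization, as the values show: whole numbers, 1 value per sequence repeated at each of its places. Per the deposited files, sequences of 15 to 30 nt were matched to the genome with PatMaN, and the submitters' processing notes name the build TAIR9. The aligner version, its settings and adapter trimming are not given in the sources used here. Sequences that match nowhere are not listed, so all shares are of genome-matched reads.

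Each listed match was compared with the reference sequence of assembly TAIR10.1 at the same coordinates, and all nuclear and chloroplast matches were identical to it, so its gene annotation was used for positions and names. Mitochondrial coordinates differ between the builds and were used only to count mitochondrial reads. The annotation used holds no transposon features, and the sequences of the T and S transgenes are not in the reference, so neither was measured.

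A distinct sequence was counted once per library however many places it matched, and the library total was all genome-matched reads of 18 to 28 nt (1151282 to 5005968 per library). Windows of 1000 bp on chromosomes 1 to 5 took the 24-nt, or the 21 and 22 nt, reads with a single genomic place, by 5' end. For miRNA, sense reads of 20 to 22 nt in 326 MIR genes were summed over 182 families with reads, and families that share sequences (such as miR156 and miR157) were merged; TAS genes took 21-nt reads of both strands. Ribosomal reads include 3800 bp past each annotated 5.8S end on the nuclear rDNA units, and the pericentromere is the region within 2 Mb of a centromere.

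Shares were compared with exact two-sided permutation tests, whose p cannot fall below 0.333 with 2 against 2 libraries. Windows and families were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, for features with at least 10 reads in at least 2 of the fitted libraries, at a Benjamini-Hochberg adjusted p of 0.05. The shoots and the roots were fitted apart, the 3 root groups together. Shoot windows and all families were scaled by the library total, since loss of DCL3 can lower most 24-nt windows at once; root windows were scaled by TMM, since there the question is which windows depart from the rest. DESeq2 1.42.0 (Wald test) was the other tool. Sets were tested with camera and fry in limma 3.58.1, camera at a preset correlation of 0.01 and then with an estimated one. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

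The fits were checked on simulated data with known changes. For root windows, 8.22%, 72.6% and 83.1% of 2-fold, 4-fold and 8-fold changes were recovered, with 4.55% of calls false; for shoot windows the values were 1.41%, 58.7% and 75.9%, with 2.27% false. In families, 12.5%, 100% and 100% were recovered in roots and 0% at each size in shoots. Camera called 0 of 100 random sets and found a set shifted by -0.5. Read counts of replicates varied more than counting error, with a chi-square per degree of freedom of 10.1 in dcl3 shoots and 1.93 to 3.5 in the other groups.

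The comparisons, the rule for naming genes, the gene lists and most alternatives were fixed before the data were examined. An exception is the list of TAS-triggering miRNA families, which the plan does not name, so it is not counted as fixed beforehand. For each window comparison the text names up to 10 windows per direction with the largest change among those past the threshold whose groups do not overlap (chance alone separates 33.3% of windows with 2 against 2), each by its overlapping or nearest gene; where 0 passed, the 3 with the smallest p. For miRNA the rule covers up to 20 families past the threshold and the list members, of which the text gives examples. The lists are TAS genes, nutrient-responsive, silencing-feedback, developmental and TAS-triggering miRNA families, known targets of RNA-directed DNA methylation, and secondary-siRNA genes; the methylation targets took 24-nt reads of the gene and 1000 bp on both sides, and the secondary-siRNA genes took 21 and 22 nt reads of the gene, each tested together with the windows.

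Replicate numbers were checked for pairing by correlating the difference between replicates 1 and 2 across groups. In roots the correlations over 24-nt windows were 0.34, 0.187 and 0.198, and over 21 and 22 nt windows 0.518, 0.39 and 0.377; over families they were 0.236 to 0.588 among the 10 pairs of groups. The root libraries were therefore also fitted with replicate number as a block. Alternatives were other scalings, no read minimum, 500-bp windows, reads divided over all their places, all 10 libraries in 1 fit, DESeq2, other denominators, the block, and each library left out in turn; scaling by reads other than organelle, rRNA and tRNA reads was added after the data were seen. Groups of 2 are too small for a test of outlying libraries or for counting other splits of the samples.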

Results

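Small RNA was sequenced from shoots or roots of grafted Arabidopsis thaliana plants, 5 weeks after 7-day-old seedlings were joined. Grafts are written shoot/root. T and S are homozygous transgenes in Col-0, and dcl3 stands for a mutant allele of DCL3, the Dicer-like enzyme that makes most 24-nt small RNA in this plant. There were 5 groups of 2 libraries: TT/TT root, TTSS/TT root, TTSSdcl3/TT root, TTSS/TTSS shoot and TTSSdcl3/TTSSdcl3 shoot, the last called the dcl3 shoot below. Each library came from a pool of 3 to 4 grafts. Genome-matched reads of 18 to 28 nt numbered 1857024 and 1968828 in TT/TT roots, 1151282 and 1715757 in TTSS/TT roots, and 2220714 and 2149307 in TTSSdcl3/TT roots. The shoot libraries held 3051484 and 4936621 such reads for TTSS and 3478680 and 5005968 for dcl3. Values with ± are means with SD over n = 2 libraries, and levels are in CPM, read counts scaled to a common total of these reads, unless another scale is named. Exact permutation tests of 2 against 2 libraries cannot give a two-sided p below 0.333. Counting intervals and floors below cover counting error only.

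The shoots compare TTSS grafts with and without DCL3, and so give the part of the small RNA that needs this enzyme. Reads of 24 nt made up 35.2% ± 0.783 of the TTSS shoot libraries and 7.98% ± 1.44 of the dcl3 shoot libraries, a difference of -27.2 points that was larger than the spread between replicates (exact permutation p = 0.333, the smallest possible). Among 24-nt reads outside organelles, rRNA and tRNA, those left in dcl3 shoots began with A in 42.4% ± 3.73 and with G in 40.0% ± 3.19. In the other 4 groups 55.5% to 55.9% of such reads began with A. With reads of organelles, rRNA and tRNA left out, the 24-nt shares were 44.2% ± 1.79 and 5.72% ± 0.567. Of the reads in dcl3 shoots, rRNA genes took 32.7% in replicate 1 and 71.8% in replicate 2, against 20.8% and 18.2% in TTSS shoots.

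**Figure D1:**
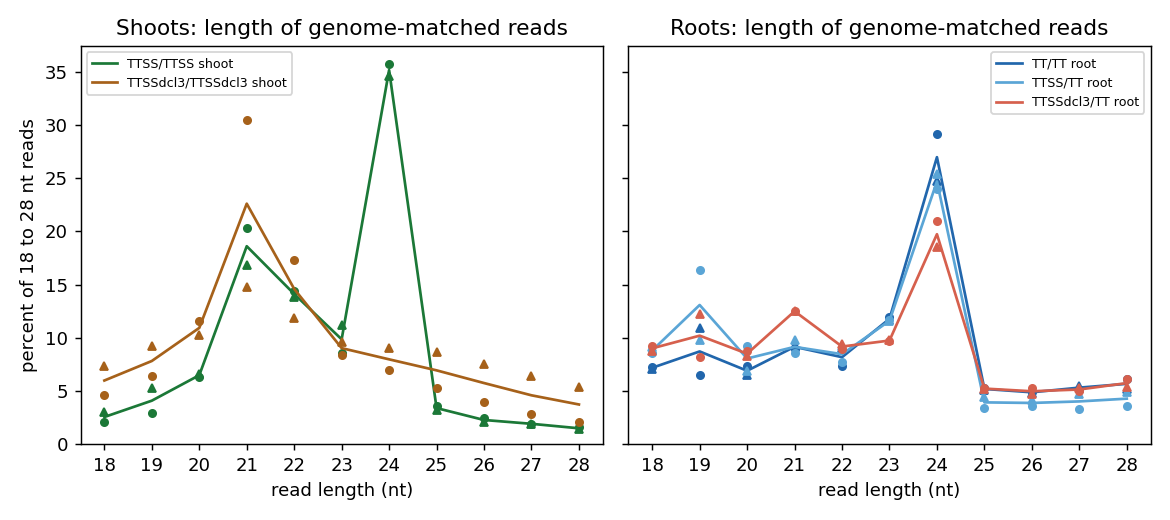
Percent of genome-matched reads of 18 to 28 nt at each length, with each library as a point (circle for replicate 1, triangle for replicate 2) and the group mean as a line. The 24-nt peak is 35.2% in TTSS shoots and 7.98% in dcl3 shoots, and it lies between 19.7% and 27.0% in the 3 root groups.

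Window by window, 24-nt RNA fell in dcl3 shoots at nearly all of the genome that could be tested. The 1000-bp window beside AT5G44410 (chromosome 5, 17890001 to 17891000) held 227 and 470 reads in TTSS shoots and 0 in both dcl3 shoots, at least 247-fold lower against a floor of 3 reads over the group. Reads were also at 0 in both dcl3 shoots near ABCG8 (at least 206-fold lower), LCR12 (184), CAM4 (150), CNGC13 (131) and AGP14 (137, chromosome 5, 22893001 to 22894000). In edgeR, 12486 of 12538 windows passed an adjusted p of 0.05, 12460 of them lower and 26 higher in dcl3 shoots, and DESeq2 called 12475. The lower windows include 2092 without a read in either dcl3 shoot; with these at their bound, the median log2 change of the lower windows was -4.36, against -4.59 as fitted over all tested windows. Scaled by TMM, which takes the typical window as unchanged and moved the median over all tested windows from -4.59 to -0.65, the test called 803 windows, 180 higher and 623 lower. Without TTSS shoot replicate 1 or replicate 2, 0 of the 1247 or 1245 windows that met the read minimum were called, although their median log2 changes were -3.71 and -3.68; the cause was not tested.

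Of the 10 windows with the largest rise among the 26 higher in dcl3 shoots, 8 lay at genes of the photosynthetic apparatus. The window at LHCB2.2 (chromosome 2, 1799001 to 1800000) held 33 reads in the dcl3 shoots and 2 in TTSS shoots, a ratio of 15.5 (95% exact counting interval 3.97 to 134.0; edgeR log2 change 3.80, SE 0.90, adjusted p = 3.0e-05). LHCA4 rose by 2.99 on the log2 scale, CAB3 by 2.92, PSAO by 2.45, LHCB4.1 by 2.39, LHCA3 by 2.35, CAB1 by 2.34 and PSBR by 2.19. HLL, with a log2 change of 2.54, and MCD1, with 2.42, were the other pair. The link to photosynthesis was noticed after the values were seen, and no enrichment test was run. Chloroplast reads were also more frequent in dcl3 shoots (24.9% against 9.39%), as were rRNA reads (52.2% against 19.5%), and without dcl3 shoot replicate 2, 11 of the 26 met the read minimum and 9 of them stayed called. The median log2 change of the 26 was 1.94 (median SE 0.65), and that of the 11 without this library was 1.45 (median SE 0.43).

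Among 8 genes listed as known targets of RNA-directed DNA methylation, SDC, FWA and AtMU1 (annotated as a pseudogene) had enough 24-nt reads to test. All 3 fell in dcl3 shoots. SDC (AT2G17690, chromosome 2) went from 21.8 ± 1.21 CPM to 1.69 ± 1.26 (edgeR log2 change -3.75, SE 0.80, list-adjusted p = 4.0e-06). FWA (AT4G25530) went from 35.8 ± 2.40 to 1.51 ± 0.717 CPM, a log2 change of -4.59, and AtMU1 had a log2 change of -5.27 (SE 1.02). The counts were 0 risen and 3 fallen adjusted over the list alone, and the same 3 when adjusted with all windows; ROS1, MEA, EVD, SUP and FLC were not tested. With TMM 0 of the 3 passed and SDC had a log2 value of 0.28.

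At 21 and 22 nt the difference between the shoots depended on the scaling. The 21-nt share was 22.6% ± 11.1 in dcl3 shoots and 18.6% ± 2.44 in TTSS shoots. With organelle, rRNA and tRNA reads left out it was 39.8% ± 9.65 against 21.7% ± 3.72, and the 22-nt share 15.9% against 13.5%, both without overlap (exact permutation p = 0.333, the smallest possible). The windows with the smallest p were at AT3G30120 (0 reads in both dcl3 shoots, 10 and 62 in TTSS shoots), at AT4G11020 (45 and 17 against 0 in both) and near FED A (307 bp away, 0 in both against 10 and 40). EdgeR called 0 of 4290 windows, with 91 at an unadjusted p under 0.05 and 0 by DESeq2, and the smallest adjusted p was 0.575. Of the windows that lost 24-nt RNA, 3697 could be tested at 21 and 22 nt; 0 were called either way, and their median log2 change was 0.30 (quartiles -0.47 and 0.85). All lost windows together had 39.0% and 34.6% of their 18 to 28 nt reads at 21 nt in dcl3 shoots, against 13.5% and 10.5% in TTSS shoots, as their 24-nt reads fell. Without dcl3 shoot replicate 1 the count was 7, 6 of them lower. The median over all windows moved with single libraries, to -0.79 without dcl3 shoot replicate 1 and 1.16 without TTSS shoot replicate 2. Scaled without organelle, rRNA and tRNA reads, a choice made after the data were seen, 604 windows passed, 571 higher and 33 lower in dcl3 shoots, and the median log2 change over all windows was 1.26 in place of 0.29. TMM called 17 windows (15 lower), DESeq2 size factors 18 (16 lower) and a fit of all 10 libraries 18 (17 lower).

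For miRNA families and TAS genes, the sources of trans-acting siRNA, edgeR called 0 of 109 between the shoots, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. The lowest p belonged to miR838 (log2 -2.70), TAS3c (-2.73) and miR391 (-2.13), each with an adjusted p of 0.995. Adjusted over the list alone, 0 members passed among 8 TAS genes, 7 nutrient-responsive, 3 silencing-feedback, 12 developmental and 3 TAS-triggering miRNA families. Among 11 genes listed as sources of secondary siRNA, TIR1, AFB2 and AGO1 among them, 0 passed adjusted over the list alone in edgeR (0 at an unadjusted p under 0.05). The spread between the dcl3 shoot replicates was wide, and simulated 8-fold changes in families were recovered in 0% of cases, so differences of that size were not detectable here.

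The question asked of the roots is whether 24-nt RNA in TT roots depends on DCL3 in the grafted TTSS shoot. The 24-nt share was 19.7% ± 1.76 in TTSSdcl3/TT roots and 24.7% ± 0.979 in TTSS/TT roots, a difference of -4.96 points with no overlap between the groups (exact permutation p = 0.333, the smallest possible). It was 27.0% ± 3.11 in TT/TT roots, which leaves -7.24 points to TTSSdcl3/TT roots (p = 0.333 by the same exact test) and -2.28 points to TTSS/TT roots, which overlapped (exact permutation p = 0.667). This last value was -0.0814 without TT/TT root replicate 1 and -4.48 without replicate 2. The 21-nt share was 12.5% ± 0.00284 in TTSSdcl3/TT roots, 9.15% ± 0.871 in TTSS/TT roots and 9.16% ± 0.241 in TT/TT roots.

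Under dcl3 shoots, root 24-nt RNA fell at 33 windows, scaled so that the typical root window was equal. AT4G03824 (chromosome 4, 1783001 to 1784000) held 0 reads in both TTSSdcl3/TT roots and 57 and 152 in TTSS/TT roots, at least 67.5-fold lower, but TT/TT roots, also under shoots with DCL3, held only 3 and 0, so this window does not show dependence on shoot DCL3 alone. AGP14 had 1 read against 36, a ratio of 34.9 (exact interval 5.88 to 1420.0), and AT2G36930 (chromosome 2, 15511001 to 15512000) had 3 against 89, a ratio of 28.8 (9.53 to 142.0). At TIP (AT5G24590, chromosome 5, 8419001 to 8420000) the libraries held 4 and 4 reads against 70 and 62 (edgeR log2 change -4.02, SE 0.51, adjusted p = 0.0024). AT4G29200 fell by 3.61 (SE 0.41) on the log2 scale and the window near GIS by 3.67 (SE 0.49), followed by PHF1 (-3.95), AT2G23860 (-3.92, 2332 bp away), AT1G56630 (-3.56) and AT2G20920 (-3.42).

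Of 6179 root windows, edgeR called 34, 33 lower and 1 higher under dcl3 shoots, and DESeq2 called 32. The window that rose was at AT1G66235 (log2 1.78, SE 0.37, edgeR adjusted p = 0.049). With replicate number as a block, 208 windows passed, 76 higher and 132 lower, and all 34 remained among them. Scaled by all reads, the median log2 change over all windows was -0.61 in place of 0.04, and 463 windows passed. Reads of rRNA genes made up 51.7% in TTSSdcl3/TT roots and 40.4% in TTSS/TT roots, without overlap, and scaling without organelle, rRNA and tRNA reads called 62. The count changed with each library left out: it was 2 without TTSS/TT root replicate 2 and 21 without replicate 1. It was 28 without TTSSdcl3/TT root replicate 1, with 17 of the 34 kept, and 51 without replicate 2 (26 higher, 25 lower), with 22 kept. Summed over the 33 lower windows, TTSSdcl3/TT roots held 134 ± 30.6 CPM, TTSS/TT roots 1300.0 ± 68.6 and TT/TT roots 1180.0 ± 189.0. TTSS shoots held 1820.0 ± 5.34 and dcl3 shoots 22.8 ± 18.6. The windows were chosen by the gap between TTSSdcl3/TT and TTSS/TT roots in these same libraries, so its size here is no separate evidence.

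**Figure D2:**
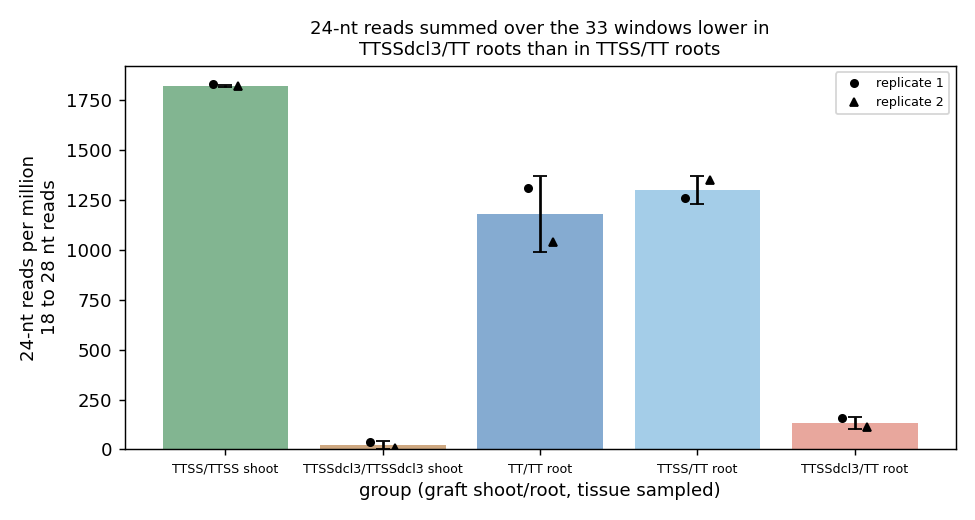
Level of 24-nt RNA, in CPM of 18 to 28 nt reads, summed over the 33 windows lower in TTSSdcl3/TT roots, with each library as a point, the group mean as a bar and SD as the error bar. Means are 134 in TTSSdcl3/TT roots, 1300.0 in TTSS/TT roots and 1180.0 in TT/TT roots. The gap between TTSSdcl3/TT and TTSS/TT roots follows from the choice of windows.

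The windows that lost 24-nt RNA in dcl3 shoots were then followed as a set in the roots. Among root windows that could also be tested in shoots, 5982 belonged to the set and 30 did not (167 others could not be tested in shoots), and the medians of their log2 changes between TTSSdcl3/TT and TTSS/TT roots were 0.02 and 0.56. Their difference of -0.54 was -0.34 without TTSS/TT root replicate 2 and -0.81 without TTSSdcl3/TT root replicate 2. Camera placed the set below the 30 other windows (limma, p = 2.1e-06 at a preset correlation of 0.01, and 0.0126 with an estimated correlation, so the call holds with both). The set holds nearly all tested windows, so camera cannot tell a fall of the set from a rise of these 30. Fry, which tests the set on its own, gave a p of 0.498 for movement one way and 0.000501 for change in either direction. The p for either direction was larger in each fit that left out a TTSSdcl3/TT or TTSS/TT root library. Such a fit leaves a group with a single library, so it cannot tell whether the call rests on the library left out. In the full fit, the set's mean of -0.01 differs in sign from its median. TMM centres this set near 0, so the value for movement one way says little. Scaled by all reads, fry gave a p of 0.0192, with a set mean of -0.57. That scaling also takes in the rRNA share, 51.7% in TTSSdcl3/TT and 40.4% in TTSS/TT roots. How much of the -0.57 comes from this make-up was not tested. Blocked on replicate number, camera at the preset correlation gave a p of 1.5e-07.

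Against TT/TT roots, which carry no S transgene in the shoot, 24-nt RNA of TTSSdcl3/TT roots fell at 55 windows and rose at 5. AT2G36930 had 3 reads against 206, a ratio of 48.0 (exact interval 16.2 to 235.0), AGP14 had 1 against 68 (47.5, 8.25 to 1900.0) and AT5G02370 had 2 against 82 (28.7, 7.69 to 241.0). TIP fell by 4.21 on the log2 scale (SE 0.50) and AT4G29200 by 3.73 (SE 0.40, edgeR adjusted p = 0.0011). Lower were also AT1G47520 (-4.35), AT3G17480 (-4.08), AT5G41490 (-3.97), AT2G23860 (-3.82) and AT3G13624 (-3.47). In TTSS/TT roots, also under shoots with DCL3, AT5G02370 held 0 reads in both libraries and AT1G47520 only 2 and 3. The falls at AT5G02370 and AT1G47520 therefore do not show dependence on shoot DCL3 alone. The 5 that rose were AT5G27900 (2.45), AT3G43828 (2.26), AT4G06636 (2.06), MEKK1 (2.01, SE 0.40, edgeR adjusted p = 0.031) and AT5G03553 (1.84).

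These 60 windows came from edgeR, where DESeq2 called 30, and the blocked count was 230 (82 higher, 148 lower), with all 60 kept. Without TTSSdcl3/TT root replicate 1 the count was 31 and without replicate 2 it was 22. Scaled by all reads it was 790, with a median log2 change over all windows of -0.70. Of the 33 windows lower than in TTSS/TT roots, 26 were also among these 55, AGP14, AT2G36930, TIP, AT2G23860 and AT4G29200 included. Independent lists of this size would share 0.294, but both lists use the same TTSSdcl3/TT libraries, so they are not separate evidence.

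TTSS/TT roots differed from TT/TT roots at 4 windows. AT4G03824 rose, with 209 reads against 3, a ratio of 96.6 (exact interval 32.6 to 472.0; edgeR adjusted p = 0.00027). AT5G02370 (chromosome 5, 503001 to 504000) had 0 reads in both TTSS/TT roots and 44 and 38 in TT/TT roots, at least 19.7-fold lower, AT5G36230 had 3 against 108 (ratio 26.0, 8.65 to 128.0), and the window near AT5G22930 fell by 2.77 (SE 0.43, edgeR adjusted p = 0.027). DESeq2 called 3 windows and the blocked fit 12, 5 higher and 7 lower, the 4 included. Without TTSS/TT root replicate 1 the count was 1 and without replicate 2 it was 0, while without TT/TT root replicate 2 it was 8; without TT/TT root replicate 1 it was 6.

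The listed methylation targets did not pass in TTSSdcl3/TT against TTSS/TT roots: 0 of SDC, FWA and AtMU1 were called by edgeR adjusted over the list alone, with 0 at an unadjusted p under 0.05. SDC had a log2 value of 0.14, which became -0.50 when scaled by all reads, and FWA had -0.94 by all reads (a p of 0.028 adjusted over the list). AtMU1 had a log2 value of 1.16 (SE 0.42) in TTSSdcl3/TT against TT/TT roots, with an edgeR p of 0.047 adjusted over the list alone and 0.281 with all windows, and by all reads 0.45 with a p of 0.356 over the list. FWA had -0.85 there by all reads, which passed over the list alone (a p of 0.047). TTSS/TT against TT/TT roots gave 0 adjusted over the list alone in edgeR (0 at an unadjusted p under 0.05). Of 10 secondary-siRNA genes tested in roots, 0 passed adjusted over the list alone in each of the 3 comparisons by edgeR, with 0, 1 and 0 at an unadjusted p under 0.05.

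At 21 and 22 nt, edgeR called 0 of 1821 root windows in each of the 3 comparisons, and DESeq2 called 0. The window at NIA1 held 2 and 2 reads in TTSSdcl3/TT roots against 13 and 22 in TTSS/TT roots (log2 -3.62, edgeR adjusted p = 0.0813), AT4G03824 held 0 in both against 11 and 25, and AT2G04110 held 76 and 82 against 8 and 8 (log2 2.67, edgeR adjusted p = 0.158). There were 158 windows at an unadjusted p under 0.05, and 49 passed with the replicate block. Between TTSS/TT and TT/TT roots the values were 32 unadjusted and 3 blocked, with AT4G03824, NIA1 (log2 3.03) and GIS (2.92) lowest in p. Between TTSSdcl3/TT and TT/TT roots they were 143 and 38, with GIS (log2 3.61, edgeR adjusted p = 0.196), AT2G04110 (2.91) and AT5G00720 (-2.62) lowest in p. Without TT/TT root replicate 1 the count was 2 in each of these last comparisons.

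Among 72 miRNA families and TAS genes in roots, edgeR and DESeq2 called 0 in each of the 3 comparisons. The lowest p under dcl3 shoots was that of miR398, at 610 ± 186 CPM in TTSSdcl3/TT roots, 320 ± 62.9 in TTSS/TT roots and 246 ± 43.4 in TT/TT roots (log2 0.93, SE 0.30, edgeR adjusted p = 0.721 against TTSS/TT; 1.31, SE 0.30, 0.251 against TT/TT). At an unadjusted p under 0.05 there were 4 against TTSS/TT, 4 between TTSS/TT and TT/TT, and 6 against TT/TT. Adjusted over the list alone, miR398 rose against TT/TT roots (edgeR, a p of 0.033), the 1 of 7 nutrient-responsive families to pass; 0 passed among 6 TAS genes, 3 silencing-feedback, 12 developmental and 3 TAS-triggering families, or in the other comparisons. Scaling by all reads left a median log2 value over all families of 0.24, 0.13 and 0.39 in the 3 comparisons.

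With replicate number as a block, 2 families passed in TTSSdcl3/TT against TTSS/TT roots, miR172 with a log2 value of -1.09 and miR398 with 0.89. In TTSS/TT against TT/TT roots the blocked fit called 4: miR172 (1.47), miR5665 (3.85), miR845 (1.60) and miR163 (0.79). In TTSSdcl3/TT against TT/TT roots it called 6: miR398 (1.30, edgeR adjusted p = 1.1e-05), miR397 (0.96), miR827 (1.89), miR845 (1.24), miR5635 (1.27) and miR5665 (3.61).

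TTSS shoots and TTSS/TT roots differ in tissue and in whether the sampled tissue carries S, and these go together. miR391 stood at 651 ± 127 CPM in shoots and 0.726 ± 0.202 in roots, where it had 2 reads (ratio 902.0, exact interval 250.0 to 7450.0). miR173, the trigger of TAS1 and TAS2, stood at 42320.0 ± 14020.0 and 378 ± 11.6 CPM (edgeR log2 change 6.81, SE 1.05), and miR167 at 3341 ± 977 and 189 ± 26.9 (log2 change 4.15, SE 0.51, edgeR adjusted p = 1.3e-12). miR172 was lower in shoots, at 245 ± 232 against 4335 ± 2069 CPM (log2 change -4.15, SE 0.54, edgeR adjusted p = 1.0e-11), as were miR846 (-3.33), miR869 (-3.07) and miR845 (-2.54). miR847 had 175 and 201 reads in shoots and 0 in both roots, at least 45.0-fold higher, and miR5650 had 24 and 40 in roots and 0 in both shoots, at least 59.4-fold lower.

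EdgeR called 67 of 104 families and TAS genes, 57 higher and 10 lower in shoots, and DESeq2 called 58. The blocked fit called 72. TMM moved the median log2 change from 1.60 to 0.08 and called 46, of which 25 were higher and 21 lower. The library total also differed in make-up: rRNA reads took 19.5% in TTSS shoots and 40.4% in TTSS/TT roots. For tRNA reads the shares were 4.45% and 14.9%, and neither pair of groups overlapped. Without TTSS/TT root replicate 1 or replicate 2 the count was 0, and without TTSS shoot replicate 1 or 2 it was 40 or 43.

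By list, all 8 TAS genes rose, also adjusted over the list alone (2 by TMM): TAS1b had a log2 change of 2.12, TAS2 of 1.82 and TAS3a of 1.94, while TAS4 and TAS3c had 0 reads in roots and were at least 12.9-fold and 7.06-fold higher. Of 12 developmental families, 10 rose, 1 fell (miR172) and miR160 was not called, with the same counts adjusted over the list alone and 6 and 2 by TMM, where miR164 (-0.41) and the merged miR165 and miR166 family (-0.10) changed sign. Of 7 nutrient-responsive families, 5 rose, miR169 fell by 1.20 and miR395 was not called, the same adjusted over the list alone; miR398 rose by 3.36 on the log2 scale, and by TMM, with 1 risen and 1 fallen, miR397 (-0.055) and miR408 (-0.31) changed sign. In the silencing-feedback list miR162 and miR168 rose and miR403 was not called, the same adjusted over the list alone, while by TMM 1 rose and 1 fell. In the TAS-triggering list the 3 families tested, miR161, miR173 and miR390, rose, the same adjusted over the list alone (1 by TMM). Membership follows the list, and whether miR161 triggers a TAS gene was not examined. The family miR390 is in both this list and the developmental list.

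**Figure D3:**
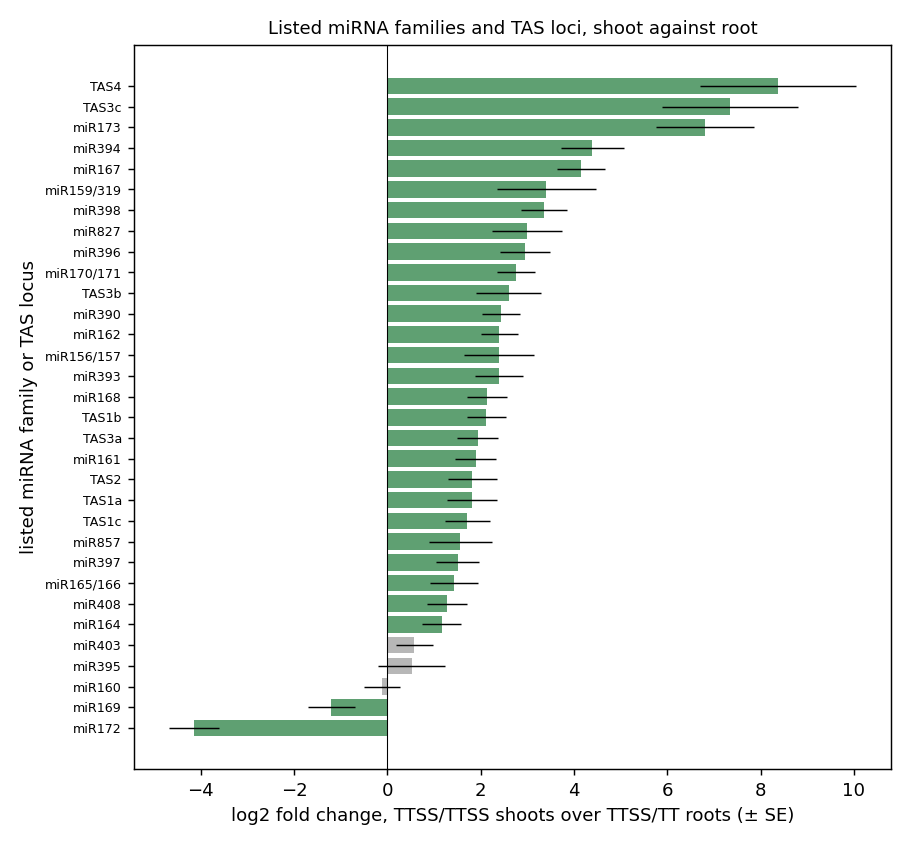
Fitted log2 change of listed miRNA families and TAS genes in TTSS shoots over TTSS/TT roots, scaled by all reads, as bars with SE, green where called by edgeR and grey where not. Fitted values of TAS4 and TAS3c, with 0 reads in roots, are no bound, and among called members miR397, miR408, miR164 and the merged miR165 and miR166 family lie below 0 when scaled by TMM.

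The 24-nt share was 10.5 points higher in TTSS shoots than in TTSS/TT roots (exact permutation p = 0.333, the smallest possible), with no overlap between the groups. With organelle, rRNA and tRNA reads left out it was -2.82 points, at 44.2% ± 1.79 against 47.0% ± 0.233. Of the nuclear 24-nt reads with a single genomic place, 25.4% ± 0.0234 lay within 2 Mb of the centromeres in dcl3 shoots. This share differed by -5.62 points from that in TTSS shoots. It was 21.4% ± 0.976 in TTSS/TT roots, and 26.7% and 23.3% in the TTSSdcl3/TT root libraries, a difference of 3.66 points between these root groups. Neither pair of groups overlapped. Reads with several places were left out of this share.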

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

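In this part the tests of carry-over and of shoot origin were chosen after the result was seen, and the root group used for carry-over was chosen with its values known.

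The effect of the dcl3 mutation was compared between the shoots that carry it and the TT roots grafted under them. In edgeR, 11146 of 12855 windows of 24-nt RNA changed differently in dcl3 shoots than in TTSSdcl3/TT roots, 11138 of them more negative in the shoots, with a median difference of -4.07 on the log2 scale. That test was scaled by all reads; with TMM it called 409, of which 326 were more negative in the shoots. On the same scaling, dcl3 shoots had 12460 lower of 12538 tested windows and roots under them 463 of 6179 by all reads, 12336 and 62 without organelle, rRNA and tRNA reads, and 623 and 33 by TMM, with AT4G03824, AGP14, AT2G36930 and TIP among the 33. The root fit had fewer reads, so the counts are not of equal power. The roots themselves carry no dcl3 allele, per the labels.

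Why those 33 windows were lower in roots was weighed. Shoot tissue, or shoot RNA of all kinds alike, carried into root samples is argued against by families found mainly in shoots. These were miR173 (42300 CPM in TTSS shoots), miR391, miR825 and miR843. They were chosen as at least 100 times higher in TTSS shoots than in TT/TT roots. In TTSS/TT roots these families kept 0.882% of their shoot level, where the windows kept 71.4%. The choice held their level low in TT/TT roots, also grafted, at 0.789%, so the low value in TTSS/TT roots is partly built in. The 71.4% may include RNA made in the root and is no measure of carry-over. Carry-over of 24-nt RNA alone was not tested. A uniformly lower 24-nt level was not tested, since TMM removes it from these windows by design. Part of the 24-nt RNA at these windows may come from the shoot: their median log2 ratio of TTSS shoot to TT/TT root, 0.65, lay at the 99.9 percentile of 10000 random lists of like level (0.14 to 0.53), and this stays a hypothesis. The fall rests on 2 TTSSdcl3/TT libraries, and without TTSS/TT root replicate 2 the count of called windows was 2, without replicate 1 it was 21.

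Reads outside the measured lengths of 18 to 28 nt were also compared with TT/TT roots. Reads of 15 nt made up 6.34% of all reads in TTSS/TT roots (6.45 and 6.24 against 5.54 and 5.21), and reads of 16 nt 17.3% (20.6 and 14.0 against 7.77 and 12.1). Reads of 17 nt made up 3.2% in TTSSdcl3/TT roots (3.44 and 2.96 against 2.95 and 2.2). Reads of 29 and 30 nt were less frequent in TTSS/TT roots, with differences of -1.59 and -2.51 points. The first 3 stood out because both libraries lay above both control libraries; that happens by chance in 16.7% of comparisons, and 10 were made. No explanation was tested for these lengths.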

How the results depend on the processing

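Scaling without organelle, rRNA and tRNA reads was added after the data were seen; the other alternatives were planned. Of the summary values, 146 were labelled as the same, 66 as moved and 2 as reversed. The same meant a count within 1.5 times the reported one, a share difference that moved by less than the SD between replicates, or a set difference with its sign and call kept, so values labelled the same could still change in size or direction balance. Examples are the miRNA calls between tissues, with 57 higher and 10 lower as reported and 25 and 21 by TMM, and the 24-nt share of TTSS/TT against TT/TT roots, at -2.28 as reported and -0.0814 without TT/TT root replicate 1. Of values for single genes and families, 1061 kept direction and call, 237 no longer passed, 32 newly passed and 9 reversed. The cause was not tested except where the construction shows it.

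The difference in 24-nt share between dcl3 and TTSS shoots was -28.8 with 20 to 25 nt reads as denominator, -35.9 for reads with a single place and -38.4 without organelle, rRNA and tRNA reads. In the same order, TTSSdcl3/TT against TTSS/TT roots gave -7.08, -7.85 and -7.92. TTSS/TT against TT/TT roots gave -4.66 and -5.3 for the last pair, and TTSSdcl3/TT against TT/TT roots -12.5 and -13.2. TTSS shoots against TTSS/TT roots gave 2.65 in the first case and reversed to -4.85 and -2.82 in the others. Leaving out each library gave -28.2 to -26.2 in shoots, -6.21 to -3.71, -4.48 to -0.0814 and -9.44 to -5.04 in the 3 root comparisons and 9.78 to 11.2 between tissues.

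For 24-nt windows in shoots, TMM called 803 and DESeq2 size factors 788, since both take the typical window as unchanged; no count minimum gave 24080 and reads divided over all their places 20441, with more windows tested. In TTSSdcl3/TT against TTSS/TT roots, scaling by all reads called 463, by miRNA reads 934 and without organelle, rRNA and tRNA reads 62, no count minimum gave 94, divided reads 14 and all 10 libraries in one fit 114. In TTSS/TT against TT/TT roots no count minimum gave 16, divided reads 2, all 10 libraries 14 and scaling without organelle, rRNA and tRNA reads 2. In TTSSdcl3/TT against TT/TT roots scaling by all reads called 790, by miRNA reads 2219 and without organelle, rRNA and tRNA reads 158; no count minimum gave 123, divided reads 20, the DESeq2 Wald test 30 and all 10 libraries 132.

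For 21 and 22 nt windows in shoots, with 0 calls as reported, TMM called 17 (15 lower), DESeq2 size factors 18 (16 lower), scaling by miRNA reads 6 (1 lower), all 10 libraries in one fit 18 (17 lower) and scaling without organelle, rRNA and tRNA reads 604, of which 571 were higher in dcl3 shoots. With no count minimum there were 2 in TTSSdcl3/TT against TTSS/TT roots and 3 in TTSS/TT against TT/TT roots.

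The replicate block, which pairs libraries by number, called 208, 12 and 230 windows of 24 nt and 49, 3 and 38 of 21 and 22 nt in TTSSdcl3/TT against TTSS/TT, TTSS/TT against TT/TT and TTSSdcl3/TT against TT/TT roots, and 2, 4 and 6 families. It takes out the difference between replicates that the root groups share. In shoots, where only 1 pair of groups could be compared and the correlations were -0.0518 and 0.00447, the block called 12213 windows of 24 nt and 0 of 21 and 22 nt.

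Of the listed methylation targets, 0 passed in shoots by TMM, where SDC reversed to 0.28, and 1 passed by all reads in TTSSdcl3/TT against TTSS/TT roots, where SDC reversed to -0.50. In TTSSdcl3/TT against TT/TT roots 1 passed in both cases, AtMU1 risen as reported and FWA fallen by all reads. Between TTSS shoots and TTSS/TT roots, by TMM miR397 reversed to -0.055, the miR165 and miR166 family to -0.10, miR408 to -0.31 and miR164 to -0.41; by DESeq2 size factors the last 3 gave -0.035, -0.24 and -0.34. Both scalings centre the families near 0.

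Leaving out each library in turn, where the lone library of a group is assumed to vary like the others, gave 0 to 12500 windows of 24 nt in shoots, where 0 of the 1247 or 1245 windows that met the minimum without a TTSS shoot library were called, with median log2 changes of -3.71 and -3.68. In roots it gave 2 to 51 in TTSSdcl3/TT against TTSS/TT, 0 to 8 in TTSS/TT against TT/TT and 22 to 88 in TTSSdcl3/TT against TT/TT. For 21 and 22 nt it gave 0 to 7 in shoots, 0 to 0 in the first and 0 to 2 in each of the other root comparisons. Families gave 0 to 0 in shoots and in roots and 0 to 43 between tissues. The difference between the set of shoot DCL3-dependent windows and other windows in roots was -0.808 to -0.34. Depth limits the roots, where 6179 windows had enough 24-nt reads against 12538 in shoots.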

Other observations

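In this part the tests of breakdown fragments, of replicate 2 alone and of a batch were chosen after the result was seen; for the 26 windows the bars of the first 2 were set with their values known, that of replicate 2 also after the value for the 24 windows was seen.

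The windows higher in dcl3 shoots include LHCB2.2, LHCA4, CAB3 and PSAO, genes of the photosynthetic apparatus, and breakdown fragments of messenger RNA are a candidate source. Reads of the other lengths of 18 to 28 nt, which played no part in choosing these 26 windows, were 3.04-fold higher in dcl3 than in TTSS shoots, close to the 3.48-fold of 24-nt reads, and both dcl3 libraries lay above both TTSS libraries (1440 and 1780 against 491 and 570 CPM). Within dcl3 shoots the 24-nt percent decides nothing, at 11.3% and 11.1%, since windows that lost 24-nt RNA had 9.29% and 8.37% there. In TTSS shoots, which have DCL3, the 26 windows had only 10.9% and 9.09% of their reads at 24 nt. Windows that lost 24-nt RNA had 66.5% and 58.1% in these libraries. In root libraries the 26 windows had 28.3% to 64.9%, so the low percent holds for shoots only. Whether the rise comes from the rRNA-rich dcl3 shoot replicate 2 alone stays open. In the 26 windows, replicate 1 held 2.72 times the TTSS shoot mean in reads of other lengths. Its 24-nt reads helped to choose these windows, and fragments of one RNA would rise together at all lengths, so this value cannot decide. In 24 windows called without replicate 1, of which 11 are among the 26, replicate 1 held 1.39 times the TTSS shoot mean (396 CPM against 298 and 272). A biological rise at these genes would look the same and was not tested.

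Replicates 1 and 2 differ alike across the groups. Of 49 well-covered families and TAS genes, 15 (30.6%) differed in one direction in all 5 groups, where independent families would give 6.25% by chance. The binomial p of 1.8e-07 takes the families as independent. They were measured in the same libraries and can move together, so this p is too small and is not read as a level of evidence. A batch shared by libraries of one replicate number is a candidate explanation. miR163 was higher in replicate 2 by 3.02, 3.62, 3.37, 1.89 and 3.99 on the log2 scale, and miR158 was lower by 1.44 to 2.14. TAS1a, TAS1c, miR822 and miR866 were lower in replicate 2 in all 5 groups. Plants grown or sampled at different times would look the same, and this was not tested.

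A pair of windows behaved as present or absent by graft. AT4G03824 had 57 and 152 reads of 24 nt in TTSS/TT roots and 30 and 34 in TTSS shoots, against 3 and 0 in TT/TT roots, 0 and 0 in TTSSdcl3/TT roots and 1 and 0 in dcl3 shoots. AT5G02370 had 44 and 38 in TT/TT roots, 1 and 1 in TTSSdcl3/TT roots and 0 or 1 in the libraries of the other 3 groups. No test was run on why.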
